A study of Mus musculus with 6 samples.

How the data were processed

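Single-cell RNA sequencing libraries of the male mouse genioglossus were made on the 10x Genomics platform from 3 control and 3 obstructive sleep apnea (OSA) samples at week 4, all labelled batch 1. Per the labels the authors aligned the reads to the mouse genome builds GRCm39 and mm39 with Cell Ranger, and the matrix headers name version 9.0.1. The deposited matrices hold raw UMI counts, whole numbers for each of 33697 genes in each called barcode. Matrices of control replicate 2 and OSA replicates 1, 2 and 3 were read, and barcode lists of all 6 libraries. The matrices of control replicates 1 and 3 were not analysed here. Each matrix was checked against its own barcode and gene lists, and 0 matrix columns lacked a sample. No genome coordinates were used.

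Barcodes with under 300 genes, under 500 UMIs or over 20% mitochondrial UMIs were removed. The gene limit removed 21, 29, 31 and 17 barcodes from control replicate 2 and OSA replicates 1, 2 and 3, and the other limits removed 0. Whether barcodes or reads were filtered on mitochondrial share earlier is not stated in the labels. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.1, which called 450, 497, 356 and 551 barcodes. These stayed in for clustering and were left out of shares and gene tests. The median number of genes per barcode was 1936, 1896, 2134.5 and 1927 in the same order. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components with 15 neighbours gave Leiden clusters at resolution 1 (python-igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Python 3.11.15). No correction between libraries was made. Immune cells were clustered a further time, and those clusters carry the letter i.

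Clusters were named from 21 marker lists chosen before the data were examined, as were the 27 gene lists, the tests, the rule for named genes and the first set of alternatives. A name needed at least 3 of a list's markers, and clusters with markers of more than 1 class or with over 50% of cells called doublets (40% for immune clusters) were left unnamed, as were clusters with low UMI totals and no marker among their leading genes and clusters that met no list. Unnamed cells were 11.1% of control cells and 12.7%, 15.04% and 13.8% of those in the OSA libraries, and they entered no gene test of a class. Class names are read from transcripts alone, so classes are written with "-like". The marker lists for myofibres, perineurial cells, mast cells, epithelium, adipocytes, chondrocytes, erythroid cells and megakaryocytes named no cluster that was kept as a class.

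For gene tests the counts were summed per library and class, since cells of 1 library are not replicates. Classes with at least 100 kept cells in each library were tested (8 classes), and 2 more with at least 30, the T and NK-like and neutrophil-like classes, were added after the data were seen. Genes were kept by edgeR's filterByExpr, scaled by TMM and tested for OSA minus control with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersions and Benjamini-Hochberg adjustment within a class at 0.05. With 1 control and 3 OSA libraries the spread came from the OSA libraries with 2 residual degrees of freedom, and the lone control was assumed to vary like them. CPM values of genes are TMM-scaled in the gene tests and unscaled class totals where libraries are listed across classes. Mean OSA levels carry the SD over 3 libraries, and log2 changes carry the SE of the fit. For a gene with 0 control counts the fold is a bound against a floor of 3 counts in the control library, and with 1 to 3 counts the ratio carries a 95% counting interval.

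The lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, in each class with at least 5 members measured, and adjusted over the 192 planned tests. The tests in classes and clusters added after the data were seen were adjusted together as a separate set. Some of that set overlap the planned classes. Camera with an estimated correlation and fry were run beside it. The haemoglobin list has 4 genes and was not testable. The endothelial activation, myogenic activation and muscle atrophy lists were called in none of the 8 planned classes, and neither was the type 17 list in the 3 of them where it could be tested.

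The named genes were the 10 with the largest rise and the 10 with the largest fall in the macrophage, fibroblast, endothelial and T and NK-like classes, and 4 of each in the others. They had to pass the threshold with a mean log2 CPM of at least 5 and all OSA libraries on the same side of the control. List members that passed were named too, and up to 4 abundant members of a described list were given as values. Genes known by clone-type symbols, and others, are not reported here.

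Cell shares carry exact binomial 95% intervals and an exact permutation test over the 4 choices of the lone library. Alternatives tried for the gene counts were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, at least 10 counts in each library, doublets kept, a mitochondrial limit of 10%, thinning to equal totals and leaving out each OSA library. For shares a minimum of 500 genes and Leiden resolution 0.5 were tried. Alternatives chosen after the data were seen were fibroblasts without cluster c27, clusters c10, c11, i1 and i8 alone, and endothelial cells with the low-UMI cluster c8. Figures were drawn with matplotlib 3.10.9.

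The gene test was tested on simulated data with the depth of each class, the spread shared by its genes at a given level, and 200 genes changed. In macrophages it recovered 4.69% of 2-fold, 54.8% of 4-fold and 77.4% of 8-fold changes, with 7 false calls among 92. Endothelial-like cells gave 46.9%, 84.4% and 95.2%, fibroblast-like cells 19.1%, 78.8% and 90.2%, and T and NK-like cells 9.68%, 67.2% and 93.0%. In neutrophil-like cells it recovered 0% of 2-fold, 2% of 4-fold and 21.7% of 8-fold changes. No simulated gene had a wider spread of its own, and no simulated library differed in cell makeup. Recovery in the real data may therefore be lower, and a count of 0 does not exclude large changes.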

Results

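The genioglossus, the tongue muscle that draws the tongue forward and helps to hold the upper airway open, was profiled by droplet single-cell RNA sequencing in male mice. Samples came from a control group and from a model of obstructive sleep apnea (OSA), the disorder of repeated airway collapse during sleep, and both were taken at week 4. There were 3 control and 3 OSA libraries, and all 6 carried the label of batch 1. The labels do not say how the model was made or whether each library was a separate animal, so the p-values measure the spread between these libraries and not necessarily that between animals. Count matrices were read for control replicate 2 and OSA replicates 1, 2 and 3, and those of control replicates 1 and 3 were not analysed here. The matrices held 70217449 UMIs in control replicate 2 and 78935595, 74007957 and 82184913 UMIs in OSA replicates 1, 2 and 3, with medians of 4111, 3889, 4879 and 4579 UMIs per barcode. After filtering, 13248 control cells and 15217, 12231 and 13759 OSA cells were kept. No 2 of these libraries were copies of each other, since every pair differed beyond sampling noise over the genes, with a chi-square per degree of freedom of 43.9 to 261.

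The number of barcodes per library was the value held for all 6 libraries. Control libraries listed 13218 ± 684 barcodes (SD, n = 3) and OSA libraries 14229 ± 1565 (SD, n = 3). The difference of 1012 barcodes gave p = 0.4 in an exact two-sided permutation test, in which 3 libraries against 3 cannot go below 0.1, so no difference in cell recovery was detectable.

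The first question was which cell types made up the muscle's mononuclear fraction in each group. Immune classes together took 3.43% of control cells and 4.46%, 8.78% and 15.02% of the cells in OSA replicates 1, 2 and 3. Neutrophil-like cells were 0.317% of control cells (exact binomial 95% interval 0.229 to 0.428) against 2.31% ± 1.497 (SD, n = 3) in OSA, with 1.16%, 4.01% and 1.77% in the OSA libraries. The difference of 1.997 percentage points was 1.15 without OSA replicate 2. Macrophage-like cells were 1.34% of control cells (1.15 to 1.55) against 5.11% ± 4.41 (SD, n = 3), with 1.99%, 3.19% and 10.2% in the OSA libraries. Monocyte-like cells, the blood precursors of many tissue macrophages, were at 0.128% in the control and 0.315%, 0.303% and 0.887% in the OSA libraries, and dendritic-like cells at 0.0981% and 0.145%, 0.376% and 0.734%. Without OSA replicate 3 the difference from the control went from 3.77 to 1.25 percentage points for macrophage-like cells, from 0.373 to 0.181 for monocyte-like cells, from 0.320 to 0.162 for dendritic-like cells and from 5.99 to 3.18 for all immune classes. B and plasma-like cells went the other way, with 0.574% of control cells (0.452 to 0.718) against 0.166% ± 0.0451 in OSA.

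Among the stromal classes, tenocyte-like cells, the fibroblast relatives of tendon, were 1.77% of control cells (1.55 to 2.01) and 3.47% ± 0.802 (SD, n = 3) of OSA cells. Schwann-like cells, the glia of peripheral nerve, were 8.87% of control cells and 8.14%, 3.64% and 3.74% in the OSA libraries. Satellite-like cells, the muscle stem cells, lay at 2.03% in the control (1.80 to 2.29) and 2.21% ± 0.101 in OSA. Endothelial-like cells (36.8% and 30.4% ± 9.58), fibroblast-like cells (19.0% and 20.7% ± 5.77) and lymphatic endothelial-like cells (0.891% and 1.35% ± 0.710) had control shares inside the range of the OSA libraries. Mural-like cells, the pericytes and smooth muscle cells of vessel walls, were at 16.1% against 13.5% ± 1.64. Choosing each library in turn as the lone one gives an exact permutation test that cannot go below p = 0.25. That value was reached by the B and plasma, tenocyte and Schwann classes, p was 0.5 for the neutrophil, macrophage, monocyte, dendritic, mural and satellite classes, and none could be called. The intervals cover counting error only.

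**Figure D1:**
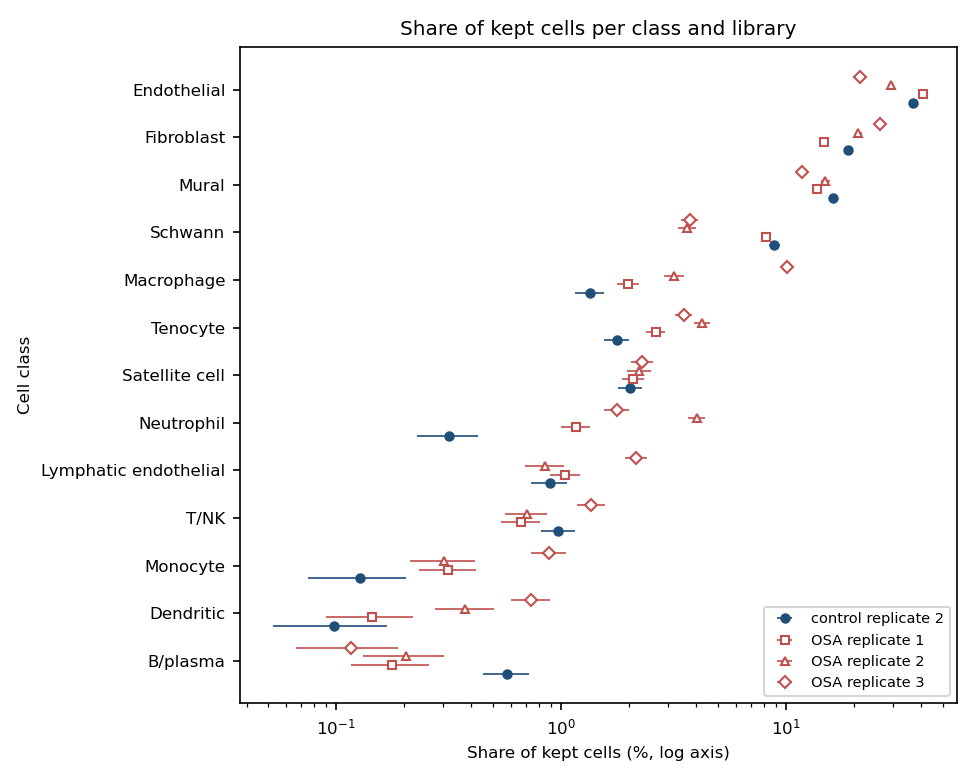
Share of kept cells (percent, log axis) in each cell class, with 1 symbol per library and bars for the exact binomial 95% interval; the filled circle is control replicate 2 and the open symbols are the 3 OSA libraries. The control share of neutrophil-like cells, 0.317%, lies below all 3 OSA libraries, and that of B and plasma-like cells, 0.574%, lies above them.

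Within the immune cells the same libraries differed in makeup. T and NK-like cells were 28.4% of control immune cells (24.3 to 32.7) and 10.7% ± 3.71 (SD, n = 3) of OSA immune cells, and B and plasma-like cells were 16.7% (13.4 to 20.5) and 2.36% ± 1.60. Both control values lay above every OSA library, which gave p = 0.25, the smallest the exact permutation test allows. Of all kept cells, T and NK-like cells were 0.974% in the control and 0.664%, 0.703% and 1.36% in OSA replicates 1, 2 and 3. The control value lay inside that range, so their lower share of immune cells was not a lower share of all cells. Neutrophil-like cells were 9.23% of control immune cells and 26.1%, 45.6% and 11.8% in the OSA libraries. Most of those of OSA replicate 2, 363 of 490, belonged to cluster i13, led by Ngp, Ltf and Camp, transcripts of granulocytes that are still maturing, and that cluster held 0 of 42 control neutrophil-like cells. Macrophage-like cells were 39.1% of control immune cells, inside the OSA range of 36.3% to 67.6%.

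In macrophage-like cells Spp1 and Saa3 were among the genes that rose in OSA, and Retnla, Folr2 and both Cd209 genes were among those that fell. Spp1, which encodes the secreted matrix protein osteopontin, went from 4.55 CPM (counts scaled to the library's class total) to 1095 ± 197 (SD, n = 3), a log2 change of 7.90 ± 0.54 (SE, adjusted p = 0.000645). Retnla, a marker of alternative macrophage activation, fell from 16599 to 2203 ± 789 CPM (log2 change -2.91 ± 0.38). The lectin receptor genes Cd209f (-3.73 ± 0.47) and Cd209d (-3.50 ± 0.26), the folate receptor gene Folr2 (-2.38 ± 0.30) and the chemokine gene Ccl24 (-2.29 ± 0.39) fell with it. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 36 genes rose and 79 fell among 12183 tested, at adjusted p under 0.05. Without OSA replicate 1 the class count was 0, with the 115 genes all in their original direction, and it was 1392 without OSA replicate 2 and 365 without OSA replicate 3.

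Other macrophage genes that rose covered several functions. Mt3, a metal-binding metallothionein, went from 9.10 to 177 ± 55.0 CPM, Tgm2, a protein-crosslinking transglutaminase, from 19.7 to 177 ± 50.4, and Rapgef4, a cyclic AMP-regulated exchange factor, from 4.55 to 127 ± 34.6. The matrix protein gene Thbs1 (log2 change 3.48 ± 0.45), Clec4e, which encodes a receptor for glycolipids (3.42 ± 0.60), and the lymphocyte-antigen gene Ly9 (3.30 ± 0.57) also rose. For genes with 1 to 3 control counts the ratio carries a counting interval. It was 427 (76.6 to 16856) for the acute-phase gene Saa3 and 65.5 (22.4 to 317) for the membrane-bound metalloproteinase gene Mmp14. Ccdc138, Tmod1, Dlg4, Selenbp1 and the complement gene C4b completed the 10 named genes that fell, with log2 changes of -2.42 to -2.22.

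**Figure D2:**
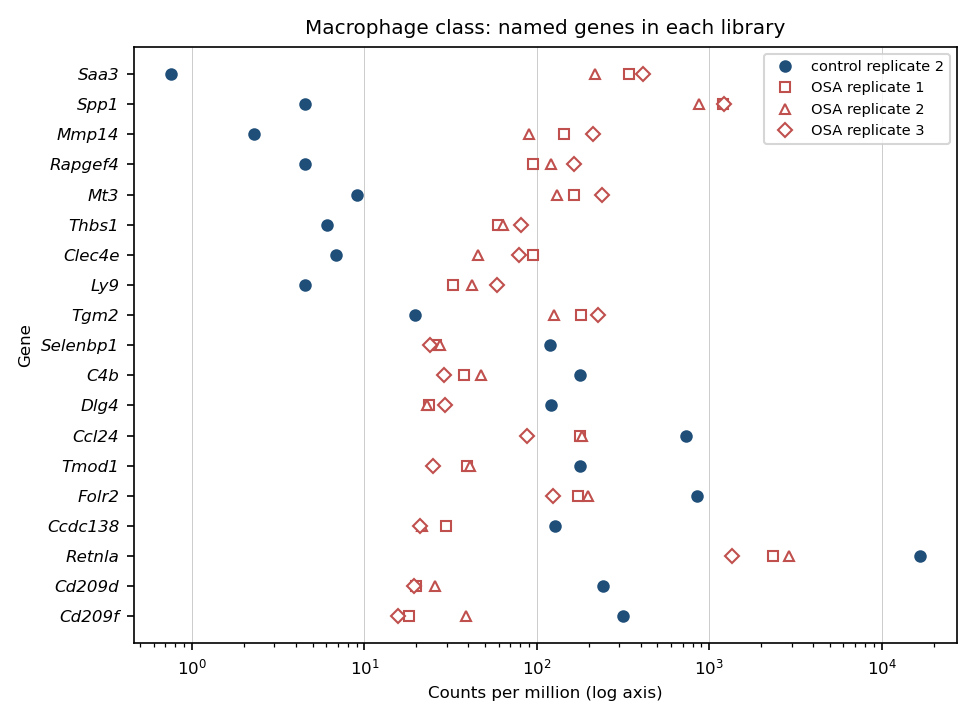
CPM (scaled counts, log axis) of named genes of the macrophage class, with 1 symbol per library; the filled circle is control replicate 2 and the open symbols are the 3 OSA libraries. Spp1 lies at 4.55 in the control and at 867.6 or more in each OSA library, and Retnla lies at 16599 in the control and at 2909 or less in each OSA library.

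The lists fixed for macrophages moved in both directions. Of 12 lipid-associated macrophage genes, 11 were higher, 1 rose (Spp1) over all genes tested and 8 rose when adjusted over the list alone (median log2 change 2.31, camera adjusted p = 1.97e-05, and adjusted p = 0.859 with an estimated correlation). Ctsd, a lysosomal protease gene, was at 298 and 2663 ± 1383 CPM and Apoe, a lipoprotein gene, at 6819 and 6443 ± 3286, neither past the threshold. Of 12 genes of MHC class II presentation, 11 were lower, 1 fell (H2-DMa, -1.62 ± 0.29) and 10 fell when adjusted over the list alone (adjusted p = 0.000122, and 0.859 with an estimated correlation). Cluster i6, led by H2-Ab1, H2-Eb1, H2-Aa and Cd74 and with 27 control and 87, 59 and 121 OSA cells, was left unnamed because markers of another class led it although its best match was macrophages, so its cells are not in the tested class. Of 17 alternative activation genes 13 were lower, and Retnla, Folr2 and Clec10a fell (median -1.61, adjusted p = 0.00200, and adjusted p = 0.859 with an estimated correlation). Of 23 hypoxia response genes 18 were higher, the glycolytic gene Pgk1 (1.87 ± 0.33) and the cytokine gene Mif (1.93 ± 0.36) rose, and 10 rose when adjusted over the list alone (adjusted p = 0.00102, and 0.859 with an estimated correlation). The hypoxia list was called in no other of the 8 planned classes by camera, and the difference between classes was not tested.

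Egr1, Hspa1b, Irf1 and Isg15 fell in macrophages. Of 19 immediate early genes 17 were lower, Egr1 fell from 889 to 296 ± 55.1 CPM, and 14 fell when adjusted over the list alone (median -1.03, camera adjusted p = 3.43e-05, and adjusted p = 0.859 with an estimated correlation). The heat shock and dissociation list had 10 of 12 genes lower, with Hspa1b at -1.57 ± 0.28, the glucocorticoid response list had 12 of 13 lower, and the interferon list had 13 of 21 lower, with Irf1 at -1.90 ± 0.29 and Isg15 at -1.58 ± 0.29 (adjusted p = 0.0219, 0.00552 and 0.00654, and each 0.859 with an estimated correlation). Higher lists were extracellular matrix (22 of 25 genes, adjusted p = 0.000442), mitochondrially encoded transcripts (12 of 12, 0.00189), neutrophil granule (14 of 14, 0.00710), antioxidant genes (13 of 17, 0.0373), nuclear-encoded oxidative phosphorylation (39 of 40, 0.00345) and cell cycle (17 of 19, 0.0312). None of these passed the threshold with an estimated correlation, where their adjusted p ran from 0.859 to 0.925. Cluster i17, led by Top2a, Mki67 and the granule gene Prtn3 among others, held 12.6% of the macrophage-like cells of OSA replicate 2. It held 1.69% of those in the control and 2.64% and 1.36% in OSA replicates 1 and 3. The cell cycle and granule lists were not tested without that cluster. Mitochondrial transcripts were at a median of 0.0155% to 0.0663% of UMIs per barcode, so that list rests on few counts, and whether mitochondrial reads were removed earlier is not stated in the labels.

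Different clusters held most macrophages in the groups, and the values above compare those mixtures. Cluster i1 held 79.2% of the control macrophages and 27.4%, 30.3% and 11.6% of those in the OSA libraries, while clusters i18, i20, i21 and i22 held 3.93% against 64.4%, 46.7% and 85.3%. Spp1, Mt3 and Saa3 lead 2 of the latter clusters and Retnla, Folr2, Ccl24 and both Cd209 genes lead i1, so their class levels and this makeup are the same measurement. Within cluster i1 alone, a test added after the data were seen, 23 genes rose and 15 fell, among them Retnla (-1.45 ± 0.28), Cd209f (-1.59 ± 0.26), Cxcl2 (1.18 ± 0.29), a neutrophil-attracting chemokine gene, and C3 (2.22 ± 0.47). Control neutrophil-like cells held Cxcl2 at 13743 CPM, and the source of its transcripts in i1 was not tested. The i1 count was 72 without OSA replicate 1 and 20 without OSA replicate 2.

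T and NK-like cells, a class added after the data were seen because it held 86 to 187 cells per library, gained type 17 genes and lost cytotoxic genes. Il17a, the cytokine that names type 17 lymphocytes, had 0 control counts and 59.3 ± 36.7 CPM (SD, n = 3) in OSA, at least 10.5-fold higher against a floor of 3 counts in the control library. Trgc1, a constant segment of the gamma-delta T cell receptor, was at least 12.5-fold higher by the same rule, and Il23r, the receptor for the cytokine that sustains type 17 cells, was 38.1 times higher (6.84 to 1506). Of 10 type 17 and regulatory genes all were higher, 6 rose over all genes tested and 9 when adjusted over the list alone (camera adjusted p = 8.13e-11, and adjusted p = 0.924 with an estimated correlation). Il1r1 (2.30 ± 0.40), Blk (2.19 ± 0.41), Ikzf2 (1.88 ± 0.44) and Ccr6 (0 control counts, at least 4.09-fold higher) were the other list members that rose.

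Of 11 cytotoxic lymphocyte genes 10 were lower in the same class and 5 fell, 7 when adjusted over the list alone (camera adjusted p = 9.22e-08, and adjusted p = 0.924 with an estimated correlation). Gzma, a granule protease gene, fell from 1713 to 423 ± 40.2 CPM, the pore-forming gene Prf1 from 264 to 57.8 ± 11.6, the chemokine gene Ccl5 from 7351 to 2204 ± 517, Nkg7 by 1.24 on the log2 scale and the transcription factor gene Tbx21 by 1.61. Also lower were Xcl1 (-2.17 ± 0.29), Ccl4 (-1.85 ± 0.30), Dapl1 (-2.49 ± 0.42), Rgs3 (-2.46 ± 0.33), Ly6c2 (-1.93 ± 0.33), Car2, Adamts14 and Patj. Pdcd1, an inhibitory receptor gene, rose from 7.55 to 78.9 ± 31.9 CPM, Frmd5 was 59.0 times higher (10.6 to 2331) and Adam12 23.2 times (6.42 to 191), and Krt83, Slc15a3, Podnl1, Mmp25 and Egln3 rose from 1 to 3 control counts. Cxcl2 (2.23 ± 0.37), Cxcl10 (2.44 ± 0.52), Gpx1 (1.55 ± 0.30) and the clock genes Nr1d1 (1.91 ± 0.53) and Bhlhe40 (1.13 ± 0.31) rose as members of other lists. Cxcl2 was at 13743 CPM in control neutrophil-like cells, and its source in T and NK-like cells was not tested. The clock list had 13 of 15 genes higher, complement 5 of 5, antioxidant genes 13 of 14 and extracellular matrix 18 of 21, and ribosomal protein genes were lower in 36 of 36 (camera adjusted p = 0.00587, 0.0154, 0.0158, 0.0118 and 0.000147, each 0.924 with an estimated correlation). The complement and extracellular matrix lists were called as higher in several other classes too, so these calls are not particular to T and NK-like cells.

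**Figure D3:**
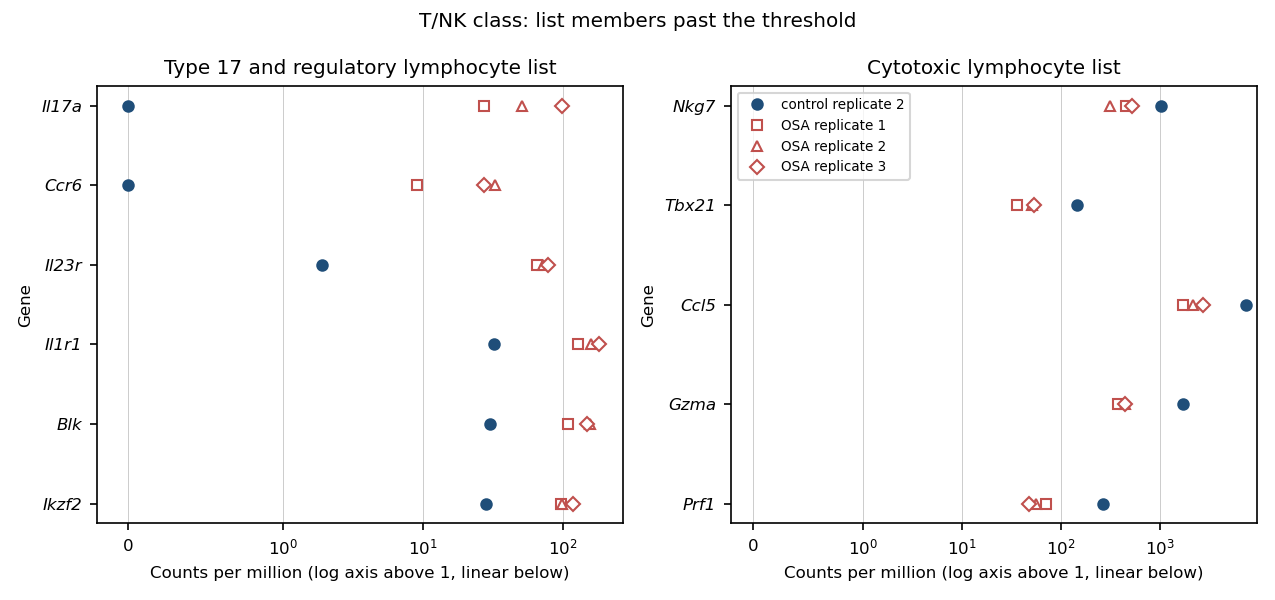
CPM (scaled counts, log axis above 1, linear below) in T and NK-like cells of the members past the threshold of the type 17 and regulatory list and of the cytotoxic list, with 1 symbol per library; the filled circle is control replicate 2 and the open symbols are the 3 OSA libraries. Il17a and Ccr6 lie at 0 in the control, and Gzma lies at 1713 in the control and at 423 on average in OSA.

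The edgeR quasi-likelihood test called 78 genes that rose and 48 that fell among 7753 in T and NK-like cells, at adjusted p under 0.05, while DESeq2 called 37 genes and edgeR 31 at 10 counts or more in each library. Cluster i11, led by Il17a, Il23r and Trgc1, held 3 of 129 control cells against 20 of 101, 24 of 86 and 54 of 187 in OSA, and cluster i4, led by Gzma, Prf1 and Xcl1, held 39 of 129 against 11, 12 and 15. Those genes and that makeup are therefore the same measurement. The count was 199 without OSA replicate 1 and 288 without OSA replicate 3, and thinning the libraries to equal totals left 59 genes, all called before.

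In neutrophil-like cells, also added after the data were seen with 42 control cells, no gene passed in edgeR's quasi-likelihood test over 5774 genes, 340 had an unadjusted p under 0.05, and DESeq2 called 0. Without OSA replicate 2 edgeR called 61 genes that rose and 10 that fell. Cluster i8, which held 40 of the 42 control cells and 106, 118 and 98 OSA cells, gave 11 genes that rose and 5 that fell when tested alone. Lcn2, an iron-sequestering granule protein gene, went from 826 to 2974 ± 452 CPM (SD, n = 3), Lgals3 from 210.3 to 782 ± 191 and Ptprj from 60.1 to 549.8 ± 167. Wfdc17 was 85.1 times higher (15.3 to 3362), Ifitm6 14.6 times (4.04 to 121), and haemoglobin Hba-a2 at least 3.35-fold from 0 control counts. The other haemoglobin transcript Hbb-bs did not share that rise in the whole neutrophil-like class. It was at 161.9 CPM in the control and 171.4, 224.4 and 129.1 in the OSA libraries. Hbb-bs was also found in the non-immune classes, and the source of Hba-a2 here was not tested. Plbd1 (-1.55 ± 0.31), Mideas (-1.67 ± 0.36), Atf3 (-1.37 ± 0.29) and Ifi27l2a (-1.17 ± 0.27) fell. Extracellular matrix transcripts were the 1 list called in the whole class, with 17 of 17 higher (adjusted p = 0.000764, and adjusted p = 0.924 with an estimated correlation). Its members are abundant in fibroblasts, and Col1a1, at 23.1 and 161 ± 68.7 CPM in neutrophil-like cells without passing, was higher in all 8 planned classes too. Without OSA replicate 3 the i8 count was 0, and without OSA replicate 1 it was 42.

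Fibroblast-like cells gave no gene past the threshold over 16717 tested in edgeR's quasi-likelihood test, and DESeq2 called 36. An unadjusted p under 0.05 was found for 678 genes, a share under 0.05 and so no excess over chance in this test. Differences between the OSA libraries widen the spread on which the test rests, so that share does not show an absence of change. The abundant collagen genes were higher without passing, with Col1a1 at 1179 and 2481 ± 1114 CPM (SD, n = 3) and Col3a1 at 1136 and 2053 ± 499. Complement genes were higher in 12 of 12, with C3 at 911 and 1736 ± 981 CPM, and extracellular matrix genes in 23 of 27 (camera adjusted p = 0.000442 and 0.00268, each 0.859 with an estimated correlation). MHC class II genes were higher in 9 of 10 and lipid-associated genes in 11 of 12 (adjusted p = 0.00564 and 0.0204, each 0.859 with an estimated correlation). Cd74 was at 17.9 and 47.9 ± 32.5 CPM in fibroblast-like cells and at like levels in tenocyte-like (13.6 and 46.0 ± 27.2) and satellite-like cells (21.8 and 49.3 ± 24.9). Transcripts of neutrophils were higher in 6 of 6 and granule genes in 13 of 13 (1.95e-05 and 1.51e-06, each 0.859 with an estimated correlation), a shift seen in other non-immune classes too. Leaving out OSA replicates 1, 2 or 3 gave 221, 187 and 32 genes.

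With cluster c27 left out of the fibroblasts, a choice made after the data were seen, 14 genes rose and 7 fell. That cluster, led by Saa3 and Serpina3n, held 0.159% of control fibroblasts and 4.41%, 0.897% and 20.3% of those in the OSA libraries. Serpina3n, a protease inhibitor of the acute phase, rose from 16.0 to 72.6 ± 21.1 CPM (SD, n = 3) and Comp, a matrix protein gene, from 13.5 to 39.95 ± 9.61. Comp is also on the tenocyte marker list, and tenocyte-like cells held a larger share of each OSA library than of the control. The source of Comp in fibroblast-like cells was not tested. Rtl4 (-1.36 ± 0.22), Stmn4 (-1.12 ± 0.22) and the interferon-induced chemokine gene Cxcl9 (-1.19 ± 0.24) fell, all with edgeR adjusted p from 0.00222 to 0.0211. Il1b rose at low level (0.935 to 5.39 ± 1.38 CPM), as did Cybb, which was 43.5 times higher (7.80 to 1718) from 1 control count. Endothelial-like cells held Il1b at a like level, 1.16 CPM in the control and 6.42, 4.59 and 8.57 in OSA replicates 1, 2 and 3.

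Cluster c10 alone gave 22 genes, with C4b (1.62 ± 0.31), the metal transporter gene Slc39a14 (1.30 ± 0.28), Nr4a2, Chst11 and Adh7 higher and Cxcl10 (-1.10 ± 0.24) and the imprinted gene Mest (-1.08 ± 0.25) lower, and there 18 of 19 cell cycle genes were lower (camera adjusted p = 1.15e-05, and adjusted p = 0.924 with an estimated correlation). Cluster c11 alone gave 32, with Snhg1 (2.44 ± 0.36), Galnt15 and Fgl2 higher and Cspg4 (-1.30 ± 0.24), Meox1, Has2, the hyaluronan synthase gene, and Heyl (-1.14 ± 0.25) lower. Serpina3n rose and Rtl4 fell in both. Without OSA replicate 1, 2 or 3 the counts were 137, 115 and 12 without c27, 247, 112 and 13 in c10, and 114, 92 and 0 in c11.

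Endothelial-like cells likewise gave 0 of 16197 genes in edgeR's quasi-likelihood test, and DESeq2 called 36. The 795 genes at an unadjusted p under 0.05 were again a share under 0.05, no excess over chance, which again does not show an absence of change. Flt1, a VEGF receptor gene, was at 4020.3 and 4316 ± 199 CPM (SD, n = 3), Kdr, the main VEGF receptor gene, at 521 and 319 ± 22.9, and the adhesion gene Icam1 at 263 and 236 ± 37.7, none past the threshold. The endothelial activation list had 8 of 17 genes higher and was not called (adjusted p = 0.416). Lists called as higher were extracellular matrix (23 of 27 genes, camera adjusted p = 4.09e-06), complement (12 of 12, 2.15e-05), MHC class II (9 of 11, 0.00787), interferon (17 of 21, 0.00959) and inflammatory genes (11 of 19, 0.00959). Lipid-associated (10 of 12), antioxidant (11 of 19), ribosomal protein (35 of 36) and oxidative phosphorylation genes (37 of 40) were also higher, and cytotoxic genes were lower in 5 of 5 (adjusted p = 0.00229, 0.0358, 0.00322, 0.0443 and 0.00345). With an estimated correlation none passed (adjusted p from 0.859 to 0.930). Complement and MHC class II transcripts were at low level in these cells, C1qb at 7.36 and 28.6 ± 20.6 CPM and Cd74 at 21.1 and 53.4 ± 30.1, and neutrophil transcripts moved with them (6 of 6 higher, adjusted p = 0.000186, and 0.859 with an estimated correlation). Leaving out OSA replicates 1, 2 or 3 gave 289, 55 and 216 genes.

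In lymphatic endothelial-like cells 3 genes rose and 1 fell among 9875. Serpina3n rose from 19.3 to 402 ± 151 CPM (SD, n = 3), Cmah, a sialic acid enzyme gene, from 29.0 to 149 ± 53.3, and Ifitm1, an interferon-induced membrane protein gene, by 12.0 times (4.11 to 58.2) from 3 control counts. Atg4a, an autophagy protease gene, fell from 480.4 to 199 ± 5.91 CPM (edgeR adjusted p = 0.0240). Extracellular matrix genes were higher in 25 of 26 (6 adjusted over the list alone), complement in 7 of 9 and antioxidant genes in 14 of 17, and interferon genes were lower in 11 of 14 (camera adjusted p = 1.77e-07, 0.000741, 0.0103 and 0.000678, each 0.859 with an estimated correlation). Myofibre transcripts, markers of muscle fibres, were higher in 9 of 10 (0.00523, and 0.859 with an estimated correlation). Counts of 133, 21 and 46 genes followed when OSA replicates 1, 2 and 3 were left out.

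Mural-like cells had 10 genes that rose and 0 that fell among 16004 in edgeR's quasi-likelihood test, and DESeq2 called 20. The 774 genes at an unadjusted p under 0.05 were a share under 0.05, no excess over chance, which does not show an absence of change. The inflammatory cytokine gene Il1b rose from 1.15 to 6.97 ± 1.53 CPM (SD, n = 3), a level far below the 9927 CPM of control neutrophil-like cells. Hp, the haemoglobin scavenger haptoglobin, at 0.535 and 20.7 ± 3.62 CPM, and Pappa2, a protease of growth factor binding proteins, at 4.82 and 21.1 ± 2.81, lay under the expression limit for naming and were chosen after their values were seen. Hp was higher in OSA in other classes too, with 84.3, 36.2 and 264 CPM in fibroblast-like cells of OSA replicates 1, 2 and 3 and 8.66 in those of the control, and control neutrophil-like cells held 1349 CPM. Thinning and a minimum of 10 counts in each library each left 4 mural genes, and Il1b did not pass there (adjusted p = 0.221 and 0.0642). Complement genes were higher in 12 of 12, ribosomal protein genes in 36 of 36 and unfolded protein response genes in 11 of 13 (camera adjusted p = 0.000384, 0.000224 and 0.00964, with 0.859, 0.895 and 0.859 with an estimated correlation). Without OSA replicates 1, 2 or 3 the numbers were 136, 85 and 52 genes.

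Tenocyte-like cells had 2 genes that fell among 12706. An unadjusted p under 0.05 was found for 579 genes, a share under 0.05 and no excess over chance. Cxcl10, an interferon-induced chemokine gene, went from 79.5 to 18.4 ± 5.25 CPM (SD, n = 3; log2 change -2.13 ± 0.30, edgeR adjusted p = 0.00125), and Epha10, named after its values were seen, from 28 counts to 1, 0 and 0. Of 19 interferon genes 12 were lower, and Irf1 was at 406 and 256 ± 28.3 CPM without passing (camera adjusted p = 0.0259, and adjusted p = 0.905 with an estimated correlation). The class gave 29, 24 and 0 genes when OSA replicates 1, 2 and 3 were left out.

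Satellite-like cells, the stem cells of muscle, had 3 genes that rose and 7 that fell among 10975. Pax7, the transcription factor gene that marks them, fell from 388 to 165 ± 21.3 CPM (SD, n = 3; log2 change -1.23 ± 0.22, edgeR adjusted p = 0.0109). The natriuretic peptide gene Nppc fell from 104 to 31.3 ± 2.86 CPM, the endothelin gene Edn3 from 186 to 79.7 ± 17.2 and Ror1, a receptor for Wnt ligands, from 1479.8 to 655 ± 41.7. Csmd1 (1.54 ± 0.29) and Ly6c1 (1.20 ± 0.25) rose, and both were higher in all 8 planned classes. Ccl5 fell from 28.5 to 6.5 ± 2.05 CPM. It is a leading gene of T and NK-like cells, where it fell too, and the source of its transcripts in satellite-like cells was not tested. The myogenic activation list had 10 of 14 genes higher and the muscle atrophy list 6 of 10, and neither was called (camera adjusted p = 0.599 and 0.969). Camera called 7 lists in this class, 3 as higher, the neutrophil granule list among them, and 4 as lower. Of the lower lists, heat shock and dissociation genes were lower in 10 of 12, immediate early genes in 14 of 19, inflammatory genes in 10 of 14 and clock genes in 13 of 16 (camera adjusted p = 0.00216, 0.0210, 0.0192 and 0.0482, each 0.859 with an estimated correlation). Leaving out OSA replicates 1, 2 and 3 gave 41, 100 and 22 genes.

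Schwann-like cells had 17 genes that rose and 3 that fell among 12601. An unadjusted p under 0.05 was found for 448 genes, a share under 0.05 and no excess over chance. Cxcl2 rose from 10.4 to 54.1 ± 21.7 CPM (SD, n = 3; log2 change 2.31 ± 0.34, edgeR adjusted p = 8.74e-08), the ribosomal protein gene Rpl39 from 125 to 476 ± 190.1 and the matrix genes Timp1 (2.02 ± 0.41) and Col3a1 (1.13 ± 0.25) with them. Neutrophil-like cells held Cxcl2 at 13743 CPM in the control and at 21955, 4549 and 36927 in OSA replicates 1, 2 and 3. The source of Cxcl2 transcripts in Schwann-like cells was not tested. Fcgr2b, an antibody receptor gene, Lyz2 and Gpnmb, which are abundant in macrophages, rose by 1.45, 1.39 and 1.33 on the log2 scale, and Ankfn1 fell by 1.01. Retnla fell from 47.2 to 20.6 ± 9.52 CPM, while control macrophages held 16599. Complement genes were higher in 11 of 11 (4 adjusted over the list alone) and unfolded protein response genes in 11 of 12 (camera adjusted p = 1.95e-05 and 0.000442, each 0.859 with an estimated correlation). The count was 69 without OSA replicate 3, 3 by DESeq2 and 3 with cells called doublets kept. Of the 9 named genes, 0 passed with doublets kept and 1, Cxcl2, passed by DESeq2.

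Some transcripts of neutrophils were higher in every class. S100a9, a calcium-binding protein gene of neutrophils, was at 3.47 CPM in control endothelial-like cells and at 24.5, 332 and 28.4 CPM in those of OSA replicates 1, 2 and 3, and at 3.30 against 23.5, 303 and 28.3 CPM in fibroblast-like cells. The neutrophil-like class in total held 2047 S100a9 counts in the control and 14522, 180060 and 14439 counts in the OSA libraries. Those totals came from 42 control cells and 177, 490 and 244 OSA cells. The S100a9 level in that class was 27610 CPM in the control and 36070, 119500 and 29590 in OSA replicates 1, 2 and 3, not past the threshold. The neutrophil granule list was called as higher in each of the 8 planned classes by camera, and in none with an estimated correlation (adjusted p = 0.859). Camera also called the extracellular matrix list as higher in macrophage, fibroblast, endothelial, lymphatic endothelial, neutrophil and T and NK-like cells, and in none of these with an estimated correlation. Its members are abundant in fibroblasts, and the source of these transcripts in the other classes was not tested. Among 8914 genes measured in all 8 classes, 22 had a log2 change over 0.5 in the same direction in every class, 20 higher and 2 lower. Rpl39 (median 2.14), the noncoding RNA Snhg1 (1.80), Ly6c1 (0.97), Adh1 (0.93), Csmd1 (1.41) and the collagen gene Col1a1 (0.86) were among the higher ones, as were Serpina3n (3.62), Hp (4.65), Il1b (2.68), Timp1 (2.17), Ifitm1 (1.89), Saa3 (6.19) and Slpi (3.54), of which all but Slpi are also given for single classes, and Retnla (-1.03) and Chordc1 (-0.80) were the lower ones. On the log2 CPM scale the same count was 20 with the control library set apart, and 3, 11 and 34 with OSA replicates 1, 2 and 3 set apart.

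**Figure D4:**
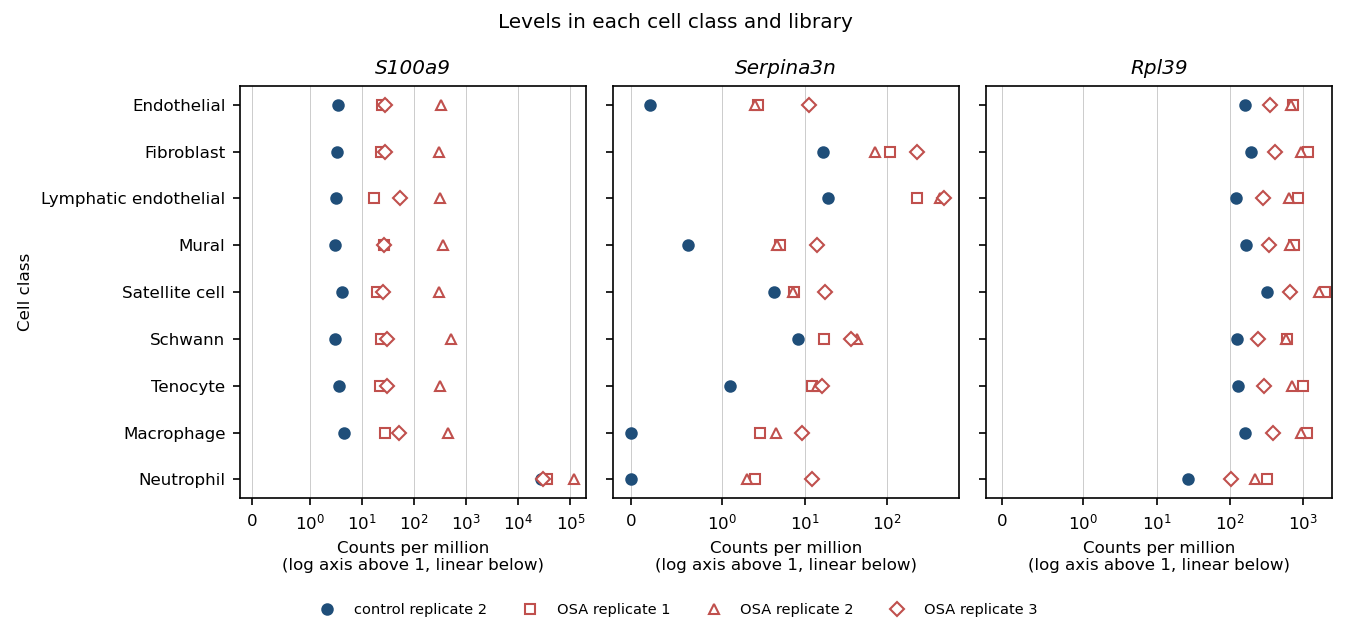
CPM (scaled counts, log axis above 1, linear below) of S100a9, Serpina3n and Rpl39 in 9 cell classes, with 1 symbol per library; the filled circle is control replicate 2 and the open symbols are the 3 OSA libraries. S100a9 takes nearly the same level in all classes of a library except neutrophils, with OSA replicate 2 the highest, while Serpina3n is highest in fibroblast-like and lymphatic endothelial-like cells.

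Of the 192 planned tests of lists in classes, camera with a preset correlation called 67, 54 higher and 13 lower. With an estimated correlation it called 0, the smallest adjusted p was 0.859 and 0 had an unadjusted p under 0.05. Chance alone would be expected to leave some of 192 tests under 0.05, so that setting could hardly call a list with these libraries. Its power was not simulated, and its results leave the 67 calls neither supported nor refuted. The rotation test fry, which asks whether a list's genes move on balance one way, also called 0, with a smallest adjusted p of 0.644 and 13 tests at an unadjusted p under 0.05.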

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

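The tests of the T and NK-like and neutrophil-like classes, of single clusters, of fibroblasts without c27 and of endothelial-like cells with c8 were chosen after the results were seen. Of 122 gene counts under another setting 45 stayed within 1.5 times the reported one and 77 moved, of 105 differences in shares 103 stayed within 1 SD between the OSA libraries, a wide limit, and 2 moved, and all 7 barcode comparisons stayed. No called result reversed. Within that limit, leaving out OSA replicate 3 took the macrophage difference from 3.77 to 1.25 percentage points and the uncalled fibroblast difference from 1.71 to -1.10, and the uncalled T and NK difference of -0.0651 became 0.0574 without OSA replicate 1 and 0.0377 without OSA replicate 2. The cause of each move was not tested except where given.

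The DESeq2 Wald test called 36 endothelial, 36 fibroblast, 410 macrophage, 20 mural, 6 satellite, 3 Schwann and 37 T and NK genes. Without a filter on low counts edgeR called 152 endothelial, 144 fibroblast, 33 lymphatic, 957 macrophage, 99 mural, 75 satellite, 31 tenocyte and 2 neutrophil genes. At 10 counts in each library, which tests fewer genes, it called 1 lymphatic, 4 mural, 3 satellite, 8 Schwann, 1 tenocyte and 31 T and NK genes. With doublets kept it called 1 fibroblast, 8 lymphatic, 52 satellite and 3 Schwann genes. Thinning to equal totals gave 1 fibroblast, 324 macrophage, 4 mural, 58 satellite, 6 tenocyte and 59 T and NK genes.

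Leaving out 1 OSA replicate gave from 55 to 289 endothelial, 32 to 221 fibroblast, 21 to 133 lymphatic, 0 to 1392 macrophage, 52 to 136 mural, 22 to 100 satellite, 22 to 69 Schwann, 0 to 29 tenocyte, 0 to 71 neutrophil and 112 to 288 T and NK genes. The ranges were 12 to 137 for fibroblasts without c27, 124 to 321 for endothelial-like cells with c8, 20 to 72 for cluster i1, 13 to 247 for c10, 0 to 114 for c11 and 0 to 42 for i8. In macrophages the 0 came without OSA replicate 1 and the 1392 without OSA replicate 2. The reported counts for the cluster settings were 21 without c27, 22 in c10, 32 in c11, 38 in i1 and 16 in i8.

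The 67 list calls became 0 with an estimated correlation and 0 with fry. The setting with an estimated correlation could hardly call any list here, so its count of 0 leaves them undecided. At Leiden resolution 0.5 the OSA minus control difference became 0.868 percentage points for monocyte-like cells and 0.578 for unnamed cells. There a monocyte-like cluster was led in part by F10 and Ass1, and a dendritic-like one by Kcnq1 and Ear2. These genes lead macrophage clusters i21 and i0 at resolution 1, so the border of the macrophage class depends on the resolution. The gene tests were not rerun at 0.5.

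The named genes kept their direction under every setting that gave them a value. Those chosen for the size of their change had all OSA libraries on the same side of the control. Leaving out 1 library could therefore hardly reverse them, so their kept direction there says little about stability. In macrophages 239 of 272 comparisons kept their side of the threshold and 33 lost it, in T and NK-like cells 241 of 269, in Schwann-like cells 53 of 90, in satellite-like cells 61 of 69, in lymphatic cells 35 of 39, in mural cells 8 of 10 and in tenocytes 9 of 10. In the cluster settings it was 15 of 21 for fibroblasts without c27, 22 of 36 in c10, 22 of 39 in c11, 48 of 71 in i1 and 20 of 30 in i8. Without OSA replicate 3, 0 of 13 named genes passed in c11, 0 of 10 in i8, 1 of 12 in c10 and 2 of 7 without c27, and without OSA replicate 2, 11 of 24 passed in i1.

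No paired analysis was possible because 1 control replicate number has a matrix, which leaves no pairs for genes, lists or shares. For barcodes, with replicate number as a replicate block, the difference of 1012 gave an exact permutation p of 0.75, where the smallest possible is 0.25. The mitochondrial limit of 10% removed 0 cells and says nothing about stability. The tallies of gene counts, shares and named genes still count it as kept. It gave 28 of the 239 kept comparisons in macrophages and 9 of the 53 in Schwann-like cells. In simulated data at the depth of the neutrophil-like class and the spread shared by its genes, 21.7% of 8-fold changes were recovered. Whether depth or spread set that limit was not separated.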

Other observations

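Written after the results were seen were the lone-library tests for T and NK-like and neutrophil-like cells and the tests of bone tissue, of blood, of free RNA for neutrophil transcripts and for Serpina3n, Saa3 and Hp, of depth in macrophages, and of the 15 macrophage genes near the endothelial level. The lone-library tests of the 8 planned classes and the tests of bone marrow, of free RNA for the macrophage genes and of the macrophage cluster mix were fixed first.

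OSA replicate 2 held most of the maturing granulocytes, with the granule genes Ngp, Ltf, Camp, Elane, Mpo and Prtn3 at 1227.8 CPM over the whole library against 9.41 in the control, 8.98 in OSA replicate 1 and 6.90 in OSA replicate 3. More red cells in that sample than in every other are argued against, since haemoglobin transcripts stood at 0.742 times the highest other library. They were at 2315 CPM in OSA replicate 2, against 1976 in the control and 3119.5 and 1381 in OSA replicates 1 and 3. Haemoglobin cannot show how many white blood cells came with the blood, so granulocytes from blood are not excluded. Bone tissue in the sample is a candidate explanation, since 4 bone cell genes under 1 CPM in the control, Bglap among them, were 37.6 times the highest other library there. Bone marrow cannot be told apart, since 0 of 4 lists of other marrow cells reached 2-fold, yet whole lists hold members that muscle also expresses, which would hide a small share. Without those members the erythroblast, B-cell precursor and megakaryocyte lists stood at 1.10, 0.563 and 1.25 times, while Igll1, a gene of B-cell precursors, had 35 counts in OSA replicate 2 and 0 in each other library, and a change in the granulocytes of that sample stays open and untested.

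Neutrophil transcripts such as S100a9 were at like levels in all non-immune classes of a library. Their highest over lowest level among those classes had a median of 2.675, so free RNA from neutrophils may account for their higher level outside neutrophils. For Serpina3n, Saa3 and Hp the fibroblast level was a median of 15.13 times the endothelial one (3.284 to 40.02), which argues against free RNA as the source of their level in fibroblasts. None of the 3 passed the threshold in the whole fibroblast class, while Serpina3n, and Hp in cluster c11, passed in subsets chosen after the data were seen, so a response of fibroblasts to OSA is open as a hypothesis.

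For the macrophage genes, lower depth of the control library is argued against, since 111 of 115 called genes were still called after thinning. Free RNA is argued against for 21 of the 36 genes that rose, which lay at least 4-fold above the endothelial level, and for the other 15, which are by definition under that limit, it cannot be told apart. A different mix of macrophage clusters cannot be told apart from a change within cells. Within cluster i1 the median change in the called direction was 0.8004 (0.67 to 0.963) against 2.244 in the class, above the bound fixed first, but that bound was wrong because 79.21% of control macrophages are the same i1 cells on which the genes were chosen. Of 105 genes measured there 104 moved in the called direction and 11 were called in both, so a loss of i1 cells, a gain of Spp1-rich cells or a change within cells could each contribute.

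Each library in turn was set as the lone one against the other 3, and 4 splits are too few for a share under 0.05. In macrophage-like cells 1 of the 4 splits reached the real count, with 115 genes for the control and at most 8 for another library, in Schwann-like cells 1, with 20 and 9, and in T and NK-like cells 1, with 126 and 14. Mural-like cells had 2, with 10 and 11, and satellite-like cells 2, with 10 and 18. Tenocyte-like cells had 3, with 2 for the control and 42 for OSA replicate 2. Lymphatic cells had 4, with 4 for the control and 24 for OSA replicate 2, and these counts, several times the real one in tenocyte-like and lymphatic cells, point to a structure of the samples beyond the groups. In the endothelial, fibroblast and neutrophil classes the real count was 0, which all 4 splits reach by definition, and the highest others were 134 and 37 genes for OSA replicate 3 and 328 for OSA replicate 2. In fibroblast cluster c11 tested alone, OSA replicate 2 as the lone library called more genes than the control did. In c10, i1, i8 and fibroblasts without c27 no OSA library reached the count of the control.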
